A study of Homo sapiens with 6 samples.

How the data were processed

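RNA of HepG2 cells was labelled with biotin as cRNA for Illumina Expression BeadChips, per the labels' protocols, with 3 arrays of DMSO control and 3 of sorafenib, each after 24 h. The authors deposited a probe intensity for each of 47323 probes and each array in 2 tables, which are not normalized per the file headers and values. A detection p-value for each probe and array stands beside it, per the file headers. The scanner software is not given in the sources used here. The deposited processed values are on a log2 scale: taking log2 of the deposited intensities and quantile normalizing them over the 6 arrays gave the same values within 5.00e-07, so they hold no background correction, and their median was 7.09 on each array. No pair of arrays held identical values. The other cell lines that the series description mentions were not analysed here.

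Groups and replicate numbers were taken from the sample titles. From the intensities, background was corrected with the normexp model of limma's neqc, with the negative controls inferred from the detection p-values and an offset of 16, followed by quantile normalization and log2. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept, which left 20120 probes. Genes were named from the platform annotation table, which gave 1 symbol to 30113 probes, several to 8 and none to 17202, and 30074 of the named probes were matched by gene number to a RefSeq gene table of assembly GRCh38.p14, which altered 0 symbols. No coordinates are given because the files name no genome build. Each of the 11542 genes was represented by its probe with the highest mean level over all arrays, and 2988 genes had more than 1 detected probe.

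Sorafenib was compared with control by limma's lmFit and eBayes on log2 values, two-sided, with Benjamini-Hochberg adjustment over all genes, and a gene was called at an adjusted p under 0.05. Fold changes are sorafenib minus control on the log2 scale, and each error is the moderated SE. A gene with no probe above background on any array of a group has only a bound there. It is given as the bright group's mean against, on each dim array, the higher of the gene's own value and the lowest value among detected probes. Before the data were examined, 34 gene lists were fixed, and the 32 with at least 3 genes tested were compared with all other genes by camera with a preset correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry were run beside it.

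The genes named in the text follow a rule fixed at the same time. It takes the 8 largest rises and 8 largest falls among called genes whose groups do not overlap, for each list the called members with the 3 largest changes and 1 in the opposite direction, and always a few fixed genes, among them P4HB, PDIA3, PDIA4, PDIA6, BRAF and KDR. In lists that did not pass camera, part of the genes the rule takes are named and the rest are given by count. ETV4, EGR1, MYC, CCND1, ARAF, DDIT3, ALB, CDKN1A and NFKBIA were named after their values were seen.

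The titles give both groups replicate numbers 1 to 3, and the labels do not say what a number stands for. Deviations from the group mean correlated at 0.304, 0.296 and 0.416 between arrays with the same number, each above the limit of 0.1 set beforehand, so the numbers were taken to pair the arrays, from these data alone. Between arrays of the 2 groups with unlike numbers they correlated at -0.338 to 0.070. Deviations cancel within a group of 3 arrays, so these correlations are not independent and do not establish a pairing. The fit without the pairing was the planned one, and the fit with the replicate number as a block was an alternative. Other alternatives were no background correction (quantile normalization of the intensities, then log2 after adding 16, an offset that the authors' values lack), normexp with an offset of 50, median scaling, cyclic loess, the authors' processed values, no filter, detection p under 0.01 on all arrays, the mean of a gene's probes, probes counted one by one, eBayes with trend and robust, array weights, and leaving out each array in turn.

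The fit was tested on simulated data for sorafenib against control, with values drawn from the means and residual SDs of the 11542 genes and 200 of them changed. Over 10 draws it recovered 39.9% of genes changed by 0.5 on the log2 scale, 84.2% of those changed by 1 and 97.3% of those changed by 2, and 5.52% of its calls fell on unchanged genes. The draws changed far fewer genes than the 2921 called in the data. They were also independent between arrays, without the correlation between arrays of equal number. The shares may therefore differ for the real comparison. The analysis used R 4.3.3, limma 3.58.1 and statmod 1.5.0, and the plots used Python 3.11.15 and matplotlib 3.10.9.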

Results

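Gene expression was measured in HepG2, a human liver cancer line that the labels class as hepatocellular carcinoma, after 24 h with sorafenib or with its solvent DMSO alone. Sorafenib is an oral inhibitor of RAF kinases and of several receptor tyrosine kinases, and its dose is given here as labelled, 3 mM. The files do not allow that unit to be checked, and micromolar doses are usual in cell culture, so the unit may be wrong. Each group had 3 BeadChip arrays, so 6 arrays entered a comparison that asks which transcripts differ with the drug. The title of the series names inhibition of protein disulfide isomerase, an enzyme family of the endoplasmic reticulum, together with sorafenib, and that family was therefore examined on its own. Mean intensity per array lay between 739 and 1050, and 19440 to 20138 of the 47323 probes were detected above background at p under 0.05. Over the 11542 genes tested, log2 values correlated at 0.991 to 0.995 within a group and at 0.975 to 0.985 between groups. The labels do not say that the replicates were separate cultures, so p-values measure the spread between these arrays, which may be technical, and the small number of arrays limits the precision.

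With sorafenib, DKK4, a secreted antagonist of Wnt signalling, rose by 3.52 ± 0.10 on the log2 scale (SE, n = 3 arrays per group; limma, adjusted p = 2.43e-05), and the chemokine CCL20 rose by 3.18 ± 0.07 (adjusted p = 1.41e-05). SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, rose by 2.97 ± 0.23, and DUSP6, a phosphatase of ERK, by 2.75 ± 0.21. The homeobox gene HOXD1 rose by 2.87, the phosphatase subunit gene PPP2R2C by 2.79, the Notch target HEY1 by 2.63 and TAGLN3 by 2.62. HEY1 and TAGLN3 were above background on 2 of the 3 control arrays. BMF, a pro-apoptotic member of the BCL2 family, fell by 2.89 ± 0.13 (adjusted p = 0.000212) and was above background on 1 of the 3 sorafenib arrays. GNMT, the glycine N-methyltransferase of liver, was not above background on any sorafenib array and, after background correction, was at least 5.21-fold lower there, and TNNC2, a troponin C gene, was at least 3.24-fold lower in the same way. The secreted phospholipase gene PLA2G1B fell by 2.52 ± 0.15, the protease gene CAPN3 by 2.37. The kinase gene PNCK fell by 2.25 and DIO1, which encodes a thyroid hormone deiodinase, fell by 2.14 ± 0.28, and the chloride channel gene CLIC3 fell by 2.11. Other detected probes gave smaller changes for SPRY4 (1.36 and 2.34), PPP2R2C (1.89) and BMF (-1.78). They gave larger ones for DUSP6 (3.13) and CAPN3 (-2.58), and -1.86 and -2.28 for DIO1.

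Over all genes, 2921 of 11542 passed an adjusted p of 0.05, which is 25.3%, with 1272 higher and 1649 lower with sorafenib. Among them 278 changed by at least 1 on the log2 scale, 104 upward and 174 downward. The 3 sorafenib arrays lay on one side of the 3 control arrays for 5179 genes, or 44.9%, where chance gives 10%. The count past the threshold was 1532 with arrays scaled to a common median, 1718 without control replicate 2, 1902 without sorafenib replicate 1 and 1711 without sorafenib replicate 2. The genes higher numbered 641, 749, 795 and 641 in those 4 fits and 845 without control replicate 1, and the genes lower 891 with median scaling, 969 without control replicate 2 and 1070 without sorafenib replicate 2. The count with a change of at least 1 was 114 without background correction, 138 with normexp on the regular probes and an offset of 50, and 124 on the authors' processed values. Without background correction the log2 changes were 1.64 for PPP2R2C, 1.41 for HEY1, 1.46 for TAGLN3, -1.50 for BMF, -1.26 for PNCK and -1.34 for CLIC3, and, under the bounds given above, -1.30 for GNMT and -0.95 for TNNC2.

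Genes known to be transcribed in response to the ERK kinase pathway were higher with sorafenib. Of 17 tested, 15 rose and none fell (16 rose adjusted over the list alone). Besides SPRY4 and DUSP6, DUSP5, a nuclear phosphatase of ERK, rose by 2.45 ± 0.53 (SE, n = 3; limma, adjusted p = 0.0179). The transcription factor genes ETV4 and EGR1 rose by 2.33 and 1.91, and MYC by 0.64. CCND1, which encodes cyclin D1, differed by 0.10 ± 0.10 (adjusted p = 0.503). The list stood above the other genes in the camera test (adjusted p = 1.13e-12), a call that was lost with an adjusted p = 0.555 with an estimated correlation. That correlation was 0.443, and camera with it gave an unadjusted p = 0.0453. DUSP5 missed the threshold without sorafenib replicate 1 (adjusted p = 0.0541) and without sorafenib replicate 2 (adjusted p = 0.0568).

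**Figure D1:**
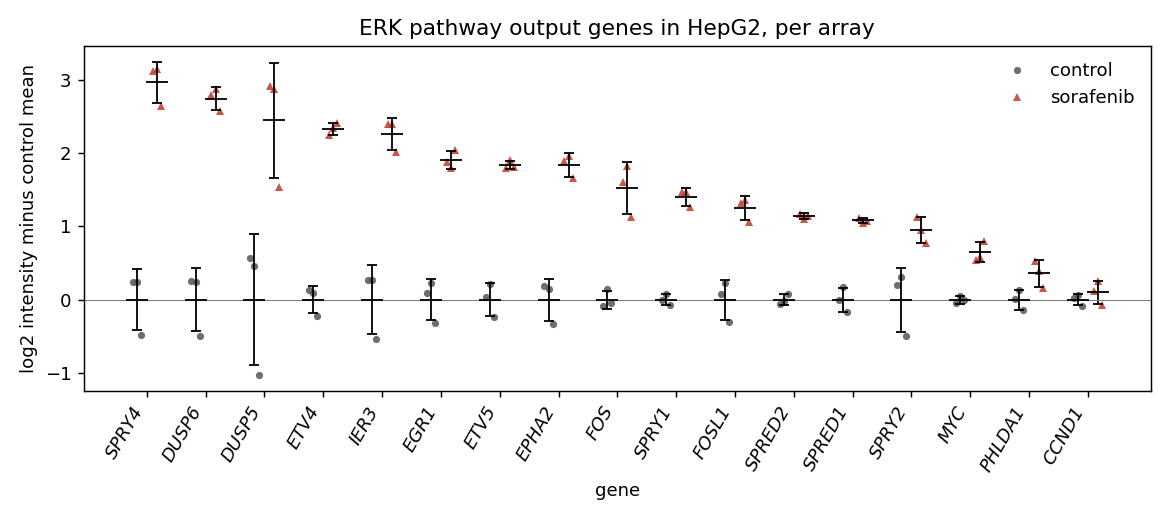
ERK pathway output genes (x axis) against the log2 intensity of each array minus the mean of the control arrays (y axis), with circles for the 3 control arrays, triangles for the 3 sorafenib arrays, and black bars for each group's mean and SD. The groups do not overlap for 16 of the 17 genes, and CCND1 is the exception.

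Of the kinases that sorafenib inhibits, 3 passed the filter. PDGFRB, a receptor for platelet-derived growth factor, was not above background on any control array and, after background correction, was at least 1.70-fold higher with sorafenib (limma, adjusted p = 0.00205). FGFR1, a fibroblast growth factor receptor, was at least 1.28-fold higher (adjusted p = 0.0133), and ARAF differed by -0.07. Without background correction the log2 changes of PDGFRB and FGFR1 were 0.45 and 0.35, and that of PDGFRB was under its bound given above. Both called genes also passed when adjusted over the list alone, and the list as a whole did not pass camera (adjusted p = 0.140), but passed it upward with median scaling (adjusted p = 0.0306). The probe of KDR was not above background on any of the 6 arrays, and BRAF was not analysed here.

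Chaperones and other genes of the unfolded protein response, which restores folding capacity in the endoplasmic reticulum, were higher with sorafenib. Of 23 tested, 13 rose and none fell (17 rose adjusted over the list alone). HSPA5, the main chaperone of this compartment, rose by 0.78 ± 0.09 on the log2 scale (SE, n = 3; limma, adjusted p = 0.0022). XBP1, a transcription factor of the response, rose by 0.69 ± 0.10, and SDF2L1, a chaperone partner, by 0.67 ± 0.08. Camera gave an adjusted p = 6.87e-08, and an adjusted p = 0.253 with an estimated correlation. With arrays scaled to a common median, 8 genes rose.

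The protein disulfide isomerase family, which forms and rearranges disulfide bonds in proteins of the secretory pathway, moved in both directions. Of 16 tested, 4 rose and 3 fell (4 and 3 adjusted over the list alone). P4HB, the family's founding member, differed by 0.12 ± 0.08 (SE, n = 3; limma, adjusted p = 0.278) and PDIA6 by -0.01 ± 0.08 (adjusted p = 0.972). PDIA4 rose by 0.38 ± 0.09 (adjusted p = 0.0215), TXNDC5 by 0.41 ± 0.10 (adjusted p = 0.0232) and TMX2, a membrane-bound member, by 0.40 ± 0.07 (adjusted p = 0.00998). ERP27 fell by 0.62 ± 0.13 (adjusted p = 0.0179) and TXNDC16 by 0.51 ± 0.12 (adjusted p = 0.0253). The only listed probe of PDIA3 was not above background on any array, which does not show whether the gene is expressed. The mean log2 difference over the family was 0.05, and the family did not stand apart from other genes (camera, adjusted p = 0.366). The test fry, which asks only whether the members move on balance in one direction, gave an adjusted p = 0.0245, and 0.139 with the replicate number as a block. Calls in this family were close to the threshold: the adjusted p of PDIA4 was 0.0737 without control replicate 2, 0.0680 without sorafenib replicate 2 and 0.0532 without sorafenib replicate 3, that of TXNDC5 was 0.0835 with the mean of its probes, 0.0624 without control replicate 2 and 0.0524, 0.0747 and 0.0533 without sorafenib replicates 1, 2 and 3, that of ERP27 was 0.0540 and 0.0515 without control replicates 1 and 2 and 0.0526 without sorafenib replicate 1, and that of TXNDC16 was 0.0520, 0.0797 and 0.0584 without control replicates 1, 2 and 3 and 0.0724 and 0.0630 without sorafenib replicates 1 and 3. With arrays scaled to a common median PDIA4, TXNDC5, TXNDC16 and TMX2 missed the threshold (adjusted p = 0.125, 0.0854, 0.0546 and 0.0715), and without background correction PDIA4 and TXNDC16 differed by 0.25 and -0.27.

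**Figure D2:**
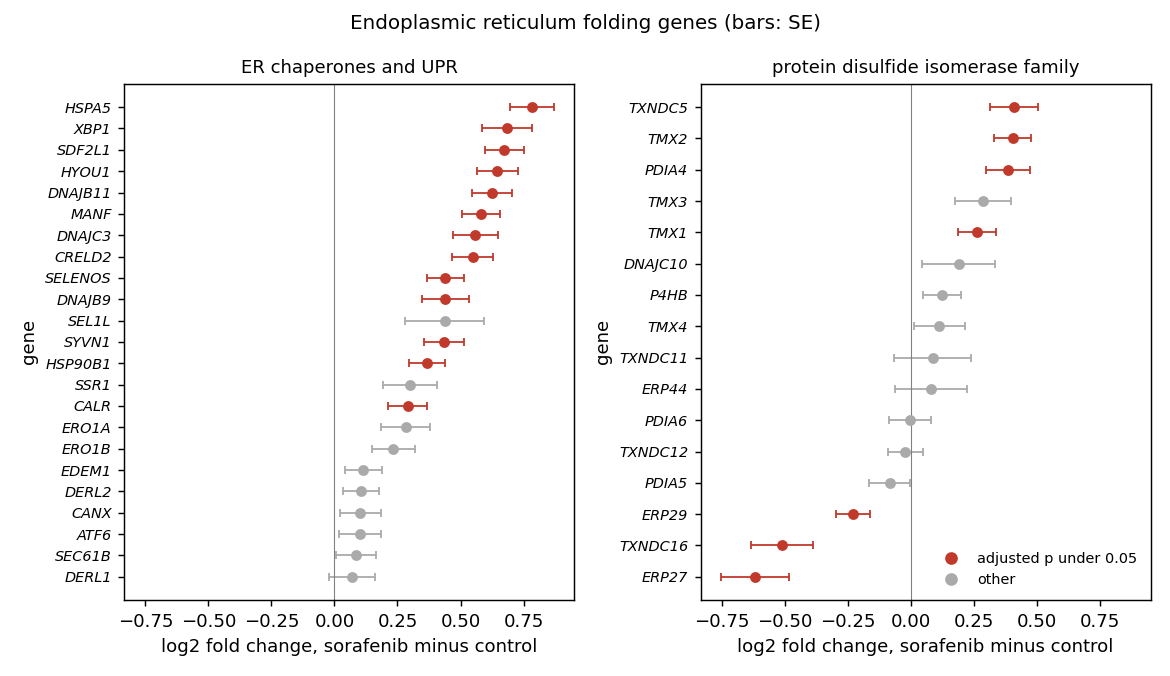
Log2 fold change of sorafenib over control (x axis) for each tested gene (y axis) of the endoplasmic reticulum chaperone list (left) and of the protein disulfide isomerase family (right), with bars for the SE. Of the chaperone list 13 genes lie past the threshold, all to the right of 0, and of the isomerase family 4 lie past it to the right and 3 to the left.

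Targets of ATF4, the transcription factor of the integrated stress response, fell more often than they rose. Of 32 tested, 4 rose and 12 fell (4 and 14 adjusted over the list alone). NUPR1, a stress-induced nuclear protein, fell by 2.05 ± 0.09 (SE, n = 3; limma, adjusted p = 0.000212) and the lipoprotein receptor VLDLR by 0.96 ± 0.15, while GDF15, a stress-induced secreted factor, rose by 1.62 ± 0.27 (adjusted p = 0.00775). DDIT3, which encodes the transcription factor CHOP, fell by 0.57 ± 0.08 (adjusted p = 0.00432). The cystine transporter gene SLC7A11 rose by 0.77 ± 0.22 (adjusted p = 0.0459). The list did not pass camera (adjusted p = 0.101), but passed it downward without control replicate 3 (adjusted p = 0.0172) and with probes counted one by one (adjusted p = 0.00499). Counted so, the several probes of a gene enter the list as separate members. With arrays scaled to a common median 5 genes fell. SLC7A11 missed the threshold with no filter on dim probes (adjusted p = 0.0697), without control replicate 2 (adjusted p = 0.0613) and without sorafenib replicates 1, 2 and 3 (adjusted p = 0.109, 0.117 and 0.0665). Its change was 0.50 without control replicate 3 and 0.45 without background correction, and that of VLDLR was -0.63 without background correction.

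Genes of DNA replication and of mitosis were higher with sorafenib. Of 20 replication and S phase genes, 10 rose and none fell (11 rose adjusted over the list alone), among them the ribonucleotide reductase subunit RRM2 by 1.22 ± 0.16 on the log2 scale (SE, n = 3; limma, adjusted p = 0.00384), the replication licensing factor CDC6 by 0.70 ± 0.08 and CDC45, a part of the replicative helicase, by 0.63 ± 0.09. Of 21 mitosis genes, 8 rose and none fell (15 rose adjusted over the list alone), among them the proliferation marker MKI67 by 0.81 ± 0.10 (adjusted p = 0.0031), the spindle checkpoint kinase BUB1B by 0.55 ± 0.15 and the mitotic kinase PLK1 by 0.54 ± 0.10. Camera gave an adjusted p = 0.000139 for replication and 2.08e-05 for mitosis, each an adjusted p = 0.555 with an estimated correlation. CDC6 differed by 0.46 without background correction. The count of replication genes that rose was 6 without control replicate 2 and 4 with arrays scaled to a common median. The count of mitosis genes was 5, 5 and 4 without control replicates 1, 2 and 3, and 4 without sorafenib replicate 2. It was 2 with arrays scaled to a common median and 5 with no filter on dim probes. It was 15 without background correction, 15 on the authors' processed values and 16 with eBayes with trend and robust together. BUB1B missed the threshold without control replicates 1, 2 and 3 (adjusted p = 0.0921, 0.0587 and 0.105), without sorafenib replicates 1 and 2 (adjusted p = 0.0584 and 0.0650), with median scaling (adjusted p = 0.0687) and with no filter (adjusted p = 0.0578).

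Genes of cholesterol synthesis and uptake were lower with sorafenib. Of 18 tested, 13 fell and none rose (14 fell and 1 rose adjusted over the list alone). The lanosterol synthase gene LSS fell by 1.13 ± 0.14 (SE, n = 3; limma, adjusted p = 0.00312), the sterol reductase gene TM7SF2 by 1.12 ± 0.17 and the mevalonate kinase gene MVK by 0.95 ± 0.16. Of 10 genes of fatty acid synthesis, 6 fell and 1 rose (6 and 1 adjusted over the list alone). ACSS2, which makes acetyl-CoA from acetate, fell by 1.19 ± 0.11 (adjusted p = 0.00117), the fatty acid desaturase gene FADS2 by 0.67 ± 0.08 and the citrate lyase gene ACLY by 0.48 ± 0.12, while SREBF1, a transcription factor of lipid synthesis, rose by 0.42 ± 0.08 (adjusted p = 0.0146). Camera gave an adjusted p = 0.000118 for cholesterol and 0.0156 for fatty acid synthesis, each an adjusted p = 0.555 with an estimated correlation, and the fatty acid list also missed the threshold with the stricter filter on dim probes (adjusted p = 0.0639). The count of cholesterol genes that fell was 8 without control replicate 3, 7 without sorafenib replicate 1, 7 without sorafenib replicate 2 and 8 with arrays scaled to a common median. The count of fatty acid genes was 2 without control replicate 2, control replicate 3, sorafenib replicate 1 or sorafenib replicate 2, and 2 with median scaling or no filter. ACLY missed the threshold in those same 4 fits (adjusted p = 0.0685, 0.0502, 0.0813 and 0.0952), with median scaling (adjusted p = 0.0654) and with no filter (adjusted p = 0.0511), and SREBF1 without sorafenib replicate 2 (adjusted p = 0.0531) and with median scaling (adjusted p = 0.0966). FADS2 differed by -0.27 without background correction.

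Interferon response genes were mostly lower. Of 11 tested, 6 fell and 1 rose (8 and 1 adjusted over the list alone). IFIT1, an interferon-induced RNA-binding protein, fell by 1.98 ± 0.16 (SE, n = 3; limma, adjusted p = 0.000835), IFIT3 by 1.14 ± 0.24 and the antiviral GTPase MX1 by 0.58 ± 0.08, while OAS1, an oligoadenylate synthetase, rose by 0.52 ± 0.10 (adjusted p = 0.0112). IFIT3 was above background on 1 of the 3 sorafenib arrays. Camera gave an adjusted p = 0.0106, and an adjusted p = 0.555 with an estimated correlation. With arrays scaled to a common median 3 genes fell and OAS1 missed the threshold (adjusted p = 0.0549), and IFIT3 missed it without control replicate 1, control replicate 3 or sorafenib replicate 2 (adjusted p = 0.0525, 0.0519 and 0.0543). Without background correction IFIT1 and IFIT3 differed by -1.23 and -0.46.

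**Figure D3:**
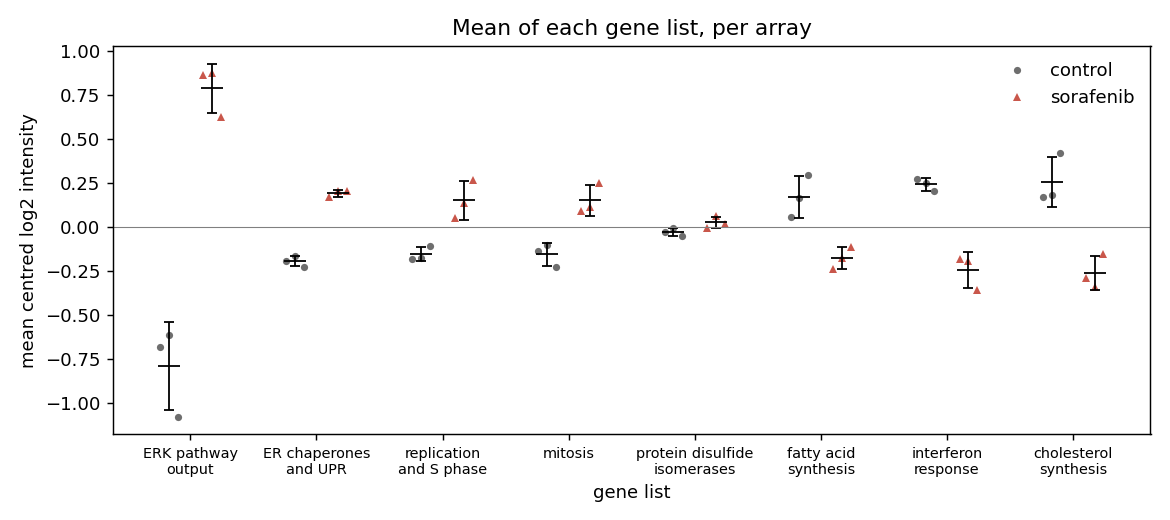
Mean over the genes of a list of the log2 intensity centred on each gene's mean over the 6 arrays (y axis), for the protein disulfide isomerase family and the lists past an adjusted p of 0.05 (x axis). Circles are the 3 control arrays, triangles the 3 sorafenib arrays, and black bars each group's mean and SD, and the groups do not overlap in any of the 8 lists, though for the isomerases the highest control array (-0.0039) and the lowest sorafenib array (-0.0033) nearly meet.

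Several genes of liver function changed without a call for their list. Of 20 secreted liver proteins, 7 fell and 2 rose (8 and 2 adjusted over the list alone; camera, adjusted p = 0.101). Apolipoprotein APOC3 fell by 1.91 ± 0.15 (SE, n = 3; limma, adjusted p = 0.000783), the fibrinogen chain FGG by 0.91 ± 0.12 and vitronectin, VTN, by 0.88 ± 0.09, while APOB rose by 0.53 ± 0.10. The other detected probe of FGG differed by -0.37. ALB, which encodes albumin, differed by -0.01 ± 0.14. Of 9 hepatocyte transcription factors, 5 fell and 2 rose (5 and 2 adjusted over the list alone; camera, adjusted p = 0.258), with a median of -0.34 and a mean of 0.01. NR0B2, a nuclear receptor that represses bile acid synthesis, rose by 2.52 ± 0.13 (adjusted p = 0.000271), and CEBPA and FOXA1 fell by 0.74 ± 0.13 and 0.70 ± 0.09. Of 11 acute phase genes, 5 fell and 2 rose (5 and 2 adjusted over the list alone), among which HPX, which encodes hemopexin, fell by 1.54 ± 0.08 (adjusted p = 0.000271), the iron hormone gene HAMP fell by 0.85 ± 0.12 and SAA4 rose by 0.75 ± 0.13. Camera gave that list an adjusted p = 0.0883, and 0.0376 with the replicate number as a block, which was lost with an adjusted p = 0.582 with an estimated correlation. Of 8 genes of the urea cycle and amino acid breakdown, 5 fell and 1 rose (5 and 1 adjusted over the list alone; camera, adjusted p = 0.101), and the argininosuccinate synthase gene ASS1 fell by 0.82 ± 0.07. Camera called the secreted proteins and the urea cycle list downward with median scaling (adjusted p = 0.0346 and 0.0330) and without sorafenib replicate 3 (adjusted p = 0.0289 and 0.0475), and the acute phase list downward without control replicate 2 (adjusted p = 0.0300) and without sorafenib replicate 3 (adjusted p = 0.0289).

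Genes of cell death and growth control moved in both directions. In the BCL2 family of apoptosis regulators 3 of 14 fell and 2 rose (3 and 2 adjusted over the list alone; camera, adjusted p = 0.770). Besides the fall of BMF, the anti-apoptotic gene BCL2L1 rose by 0.58 ± 0.11 (SE, n = 3; limma, adjusted p = 0.0119), as did MCL1 by 0.50 ± 0.12 (adjusted p = 0.0261), and the pro-apoptotic gene BOK fell by 0.52 ± 0.10. MCL1 missed the threshold without control replicates 1, 2 and 3 (adjusted p = 0.0568, 0.0641 and 0.0758), without sorafenib replicates 1 and 2 (adjusted p = 0.0709 and 0.0822) and with median scaling (adjusted p = 0.0669). Of 18 p53 targets, 4 fell and none rose (4 fell adjusted over the list alone; camera, adjusted p = 0.106), among which the sestrin gene SESN1 fell by 0.90 ± 0.09 and TP53INP1, a regulator of autophagy and cell death, fell by 0.75 ± 0.15. CDKN1A, a cell cycle inhibitor, differed by -0.20 ± 0.16.

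Genes of growth and inflammatory signalling also moved in both directions. In the list of MTOR, insulin and FOXO signalling 4 of 12 rose and 3 fell (4 and 3 adjusted over the list alone; camera, adjusted p = 0.476), among which IGFBP1, a secreted binding protein of insulin-like growth factors, rose by 2.48 ± 0.22 (SE, n = 3; limma, adjusted p = 0.000985), FOXO1 rose by 0.93 ± 0.11 and IRS1, an adaptor of the insulin receptor, fell by 0.91 ± 0.12. Of 8 genes of NF-kappa-B signalling and chemokines, 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera, adjusted p = 0.235). CCL20 was one of these, the neutrophil chemokine CXCL8 rose by 1.70 ± 0.36 (adjusted p = 0.0173), the adhesion molecule ICAM1 rose by 1.14 ± 0.18, and NFKBIA, a target of the pathway, differed by -0.19. With median scaling camera called the chemokine list upward (adjusted p = 0.0357), and without background correction IGFBP1 differed by 1.55. CXCL8 missed the threshold without sorafenib replicate 1 (adjusted p = 0.0526) and without sorafenib replicate 2 (adjusted p = 0.0547), and its other detected probe differed by 0.92. Of 10 YAP targets, 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera, adjusted p = 0.205), among which CCN2, a matricellular protein, rose by 1.64 ± 0.09 and AJUBA, a scaffold protein, fell by 0.85 ± 0.09. Of 16 glycolysis genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera, adjusted p = 0.101). Hexokinase HK2 rose by 1.74 ± 0.09 (adjusted p = 0.000271) on its brightest probe, while its other detected probe differed by 0.21 ± 0.12 and the mean of both by 0.98 (adjusted p = 0.00124). With the replicate number as a block 6 genes of that list rose.

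The remaining lists did not pass camera in the planned fit, and their calls under other settings are given here or further below. Of 18 hypoxia genes, 3 rose and 4 fell (3 and 4 adjusted over the list alone; camera, adjusted p = 0.798), among which LOX, an enzyme that crosslinks collagen, rose by 1.49 ± 0.08 (SE, n = 3) and ANGPTL4, an inhibitor of lipoprotein lipase, fell by 1.37 ± 0.18. ANGPTL4 missed the threshold without control replicate 3 (-0.16, adjusted p = 0.294) and with the stricter filter (-0.034, adjusted p = 0.85), both of which took another probe of the gene, and differed by -0.70 with the mean of its probes and -0.72 without background correction. Of 16 NRF2 targets, 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera, adjusted p = 0.568), with a median of -0.05 and a mean of 0.11. Of 8 metallothioneins, 1 rose and 2 fell (1 and 2 adjusted over the list alone; camera, adjusted p = 0.451), and their sequences are similar enough that probes may not separate them. Of 19 autophagy and lysosome genes, 2 rose and 6 fell (2 and 6 adjusted over the list alone; camera, adjusted p = 0.101), and camera called that list downward without control replicate 1 (adjusted p = 0.0488). Of 23 oxidative phosphorylation genes, 2 fell (0 adjusted over the list alone; camera, adjusted p = 0.227), and of 21 cytosolic ribosomal proteins limma called 0, and 0 at an unadjusted p under 0.05 (0 adjusted over the list alone; camera, adjusted p = 0.602). For heat shock genes the counts were 1 higher and 1 lower of 12 (0 and 1 adjusted over the list alone; camera, adjusted p = 0.568). For TGF-beta and mesenchymal genes they were 2 higher and 5 lower of 9 (2 and 5 adjusted over the list alone; camera, adjusted p = 0.278). For beta-catenin targets they were 1 higher and 3 lower of 12 (2 and 4 adjusted over the list alone; camera, adjusted p = 0.302), and 2 and 5 with the replicate block. For drug metabolism and transport they were 1 higher and 1 lower of 9 (2 and 4 adjusted over the list alone; camera, adjusted p = 0.451), and 1 and 2 with the block.

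Markers of other cell types were mostly below the filter. Of 10 markers each, 4 of leukocytes, 2 of fibroblasts and stellate cells and 1 of endothelium were tested. Of the leukocyte markers LYZ, which encodes lysozyme, rose by 0.82 ± 0.10 (SE, n = 3; limma, adjusted p = 0.00271) and no other passed (2 rose adjusted over the list alone; camera, adjusted p = 0.235). Of the fibroblast markers PDGFRB was higher and ACTA2, a smooth muscle actin, fell by 0.65 ± 0.08 (1 and 1 adjusted over the list alone), and the endothelial marker did not pass. Of 7 cholangiocyte markers, 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera, adjusted p = 0.821), with a median of -0.04 and a mean of 0.05.

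Of the 32 lists with at least 3 genes tested, 7 passed camera, 4 upward and 3 downward. None passed with an estimated correlation, where the lowest adjusted p was 0.253 and 2 lists had an unadjusted p under 0.05, and 21 passed fry. For the 7 lists that passed with the preset 0.01, the estimated correlation ran from 0.034 for the chaperones to 0.580 for mitosis. With no filter on dim probes camera also called the p53, secreted protein, autophagy and acute phase lists downward and glycolysis upward (adjusted p = 0.0473, 0.0435, 0.0434, 0.0494 and 0.0473). With probes counted one by one it called these, the ATF4, urea cycle and beta-catenin lists downward and the YAP list upward (adjusted p = 0.00499 to 0.0441). In that setting the several probes of a gene entered a list as separate members, so they are not independent evidence. Calls gained in fits with a changed setting or a left-out array were made with the preset correlation. When the arrays were regrouped into other sets of 3 and 3, camera with the preset correlation called up to 9 lists, while limma called 0 genes in each of those groupings (119 to 561 at an unadjusted p under 0.05). Those groupings mix sorafenib and control arrays, which widens their residual spread, so their 0 genes do not measure chance. They also hold the sorafenib arrays unequally on their sides, so part of the treatment difference stays in the contrast. Their list counts do not measure chance either. Of 947 further detected probes of genes past the threshold, 869 had the sign of the brightest probe, which is 91.8%. That share concerns the sign alone, not the size of a change.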

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

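The test in this part was chosen after the gene results were seen. Probes with no single listed gene symbol stayed outside the comparison of genes. Of 4842 such probes that passed the detection filter, 145 passed an adjusted p of 0.05 in limma, 56 higher and 89 lower with sorafenib than in the control arrays, which is a signal in probes that no gene count covers. The share past the threshold was 2.99%, against 21.7% of the 15278 probes with a symbol, and the median level was 6.80 against 8.89 on the log2 scale. Each set was fitted and adjusted on its own, so the same adjusted p stands for unlike unadjusted p-values in the 2 shares. The largest rise among them was 3.21.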

How the results depend on the processing

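The counts of list members and the tests of single lists other than the isomerase family under each alternative were added after seeing the data, and the other alternatives were chosen before the data were examined. The slide as a block was not run, because the files give no slide. Median scaling gave 1532 genes past the threshold (641 higher, 891 lower) and 11 lists, and 8 chaperone, 4 replication, 2 mitosis, 8 cholesterol, 2 fatty acid, 3 interferon and 5 ATF4 list genes, where the median log2 change of all genes was 0.02; the cause was not tested. Genes with a change of at least 1 numbered 114 without background correction, 138 with normexp and an offset of 50, and 124 on the authors' processed values; the cause was not tested. Mitosis genes numbered 15, 15 and 16 without background correction, on the authors' values and with eBayes with trend and robust together. Without a filter 12 lists, 5 mitosis and 2 fatty acid genes passed over 20046 genes. Lists numbered 16 with probes counted one by one, 21 by fry and 0 with an estimated correlation, and fry moved the isomerase family past the threshold (mean 0.0535, adjusted p = 0.0245, and 0.139 with the block; 0.228 to 0.555 by camera under each other alternative, and 0.582 with the block and an estimated correlation together). Leaving out 1 array gave 1711 to 2392 genes (641 to 970 higher, 969 to 1422 lower), 244 to 326 with a change of at least 1, 7 to 10 lists, an isomerase mean of 0.04 to 0.07, and 12 to 15 ERK, 11 to 13 chaperone, 6 to 10 replication, 4 to 6 mitosis, 7 to 13 cholesterol, 2 to 5 fatty acid, 5 to 6 interferon, 8 to 10 ATF4 and 7 to 8 secreted protein genes; fewer arrays were fitted. PDIA6, not called, changed sign, to 0.036 with median scaling, 0.0087 with cyclic loess, and lay between -0.073 and 0.034 without 1 array. With the replicate block 3679 genes passed (1664 higher, 2015 lower), 285 with a change of at least 1, and 8 lists, with 16 lists by fry. The block changed no call of a named gene, changed the camera call of the acute phase list alone, and moved member counts of the fixed lists by over 1.5 times only for glycolysis, beta-catenin targets and drug metabolism. Of 116 genes covered by the naming rule, 77 kept call and direction under all alternatives run and 39 did not under at least 1. The precision of dim probes is limited by their signal over background.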

Other observations

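The groups of symbols with a shared stem in this part, and the tests of the patterns that follow, were chosen after the gene and list results were seen. Of 343 groups of at least 5 tested genes, 14 passed camera, 12 upward and 2 downward, and none with an estimated correlation (adjusted p = 0.804 for each, though some had an unadjusted p under 0.05). The power of camera with an estimated correlation was not tested with these 6 arrays. Those described first were picked from the 14 by what their genes are known to do, and no theme was tested as such. Of 11 UTP genes, which process the small subunit's RNA, 8 rose and none fell (camera, adjusted p = 0.000574, and adjusted p = 0.804 with an estimated correlation). RRP genes rose in 5 of 9 cases, NOP genes in 5 of 8, and EXOSC genes, which encode the RNA exosome, in 6 of 10, with none lower (adjusted p = 0.00337, 0.0284 and 0.0228, each adjusted p = 0.804 with an estimated correlation). Probes named for small nucleolar RNAs, which guide the modification of ribosomal RNA, formed 2 groups: 25 of 51 SNORA genes rose and 1 fell (adjusted p = 2.85e-07), and 20 of 50 SNORD genes rose and 1 fell (adjusted p = 5.81e-05), both with an adjusted p = 0.804 with an estimated correlation. Named after their values were seen, RRP9 rose by 0.95 ± 0.12 (SE, n = 3; limma, adjusted p = 0.00313) and UTP15 by 0.72 ± 0.15 (adjusted p = 0.0158), while the list of cytosolic ribosomal proteins had no call. Medians of these groups stayed above 0 under median scaling and cyclic loess, where 6 and 8 UTP genes and 2 and 7 EXOSC genes rose and, with median scaling, 3 NOP genes. EXOSC genes that rose numbered 3 and 1 without control replicates 1 and 2 and 3, 1 and 3 without sorafenib replicates 1, 2 and 3, NOP genes 3 without control replicate 2 or sorafenib replicate 1, and SNORA genes 16 without control replicate 2. Many small nucleolar RNAs lie inside introns of other genes and resemble each other, so their probes may not separate them. Whether these probes reported the mature RNAs or transcripts of the surrounding genes was not tested. With no filter on dim probes the medians were 0.16 over 101 SNORA and 0.036 over 176 SNORD genes, in place of 0.45 and 0.39, and without background correction 0.24 and 0.17. The other upward groups were DDX, CDCA, NUP, IER, POLR and MCM, with medians of 0.23, 0.37, 0.21, 0.52, 0.20 and 0.30 (camera, adjusted p = 0.00337, 0.0228, 0.0228, 0.0228, 0.0284 and 0.0298), and the IFI group was lower with a median of -0.55 (adjusted p = 0.0383). These medians kept their sign under median scaling and cyclic loess. With median scaling 3 of 29 DDX, 2 of 7 CDCA, 1 of 22 NUP, 2 of 5 IER, 4 of 32 POLR and 0 of 10 MCM genes rose. The planned fit gave 8, 4, 6, 4, 9 and 4, and cyclic loess 9, 4, 7, 4, 9 and 4. The IER median was 0.34 without background correction, and the DDX median was 0.14 with no filter on dim probes. The NOL group, with a median of 0.25, did not pass (adjusted p = 0.241).

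Alpha-class glutathione transferases, which detoxify electrophiles, were lower with sorafenib. Of 5 GSTA genes 4 fell (camera, adjusted p = 0.00113, and adjusted p = 0.804 with an estimated correlation). GSTA2 fell by 1.80 ± 0.11 and GSTA1 by 1.43 ± 0.09 (SE, n = 3; limma, adjusted p = 0.000369 and 0.000392), both named after their values were seen, and the probes of these near-identical genes cannot be assumed to tell them apart. With median scaling or cyclic loess 5 of the 5 fell.

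ERK pathway output genes were higher with sorafenib, although the drug inhibits RAF kinases upstream of ERK. The tables argue against the handling of dim probes as the cause, since 16 members rose without background correction. That count alone would not decide, because calls over all genes rose too, from 2921 to 3402. Camera with the preset correlation still put the list above the other genes there (adjusted p = 6.03e-15). The tables also argue against a single array, since at least 12 rose whichever array was left out, which equals the bound set beforehand. A candidate explanation is that ERK-dependent transcription rose, as RAF inhibitors are known to do in cells with active RAS, and HepG2 is known to carry an activating NRAS mutation. A further list of 22 ERK-dependent genes, sharing none with the other, was written from general knowledge before it was tested. It was written after the gene and list results were seen, so it is no independent test. Of its genes 18 were tested, of which 14 rose and none fell (camera p = 8.61e-08, and p = 0.0143 with an estimated correlation). Its member POLR3G, which rose by 0.87, also counts in the POLR group above. Transcription of many of the ERK-dependent genes also follows other growth and stress signals. ERK phosphorylation was not analysed here, and what happened at earlier times stays open.

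Replication and mitosis genes were higher with sorafenib. Spread of growth state between samples of a group was weighed by the mean over both lists, which was higher with sorafenib by 0.23, 0.26 and 0.43 for the replicate numbers 1, 2 and 3. The smallest of these was 2.38 times the larger group SD. This does not decide, because the labels do not say that the replicates were separate cultures and the SD may be technical. That spread stays open, and a difference in density or medium between the groups stays open too, as does an effect of the drug.

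Arrays with the same replicate number deviated together from their group means. The tables argue against an intensity-dependent trend between arrays as the whole cause. Cyclic loess, which removes such trends, gave 3009 genes past the threshold against 1532 with median scaling. For numbers 1, 2 and 3 the correlations were 0.296, 0.295 and 0.420 with cyclic loess. With median scaling they were 0.276, 0.316 and 0.422. The arrays of number 3 had the lowest mean intensity of their groups (739 for control and 832 for sorafenib). Whether that bears on their correlation was not tested. A shared culture, day or slide stays open, because neither the labels nor the files give one, and no biological explanation was tested. Chance stays open too, because deviations cancel within each group and the correlations are not independent.

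Other groupings of the 6 arrays were compared with the real one. There are 10 groupings into 3 and 3, too few for a share under 0.05. The real one gave 2921 genes and 278 genes with a change of at least 1, and the highest other gave 0 of each by limma (119 to 561 genes at an unadjusted p under 0.05, against 4504 in the real one), so for both counts 1 of the 10 was as large. Each other grouping mixes sorafenib and control arrays, so the difference between treatments enters its residual spread and lowers its gene calls in advance. The 0 genes there are therefore no measure of chance. For lists past camera, the real grouping gave 7 and the highest other 9, and 4 of the 10 were as large. Each other grouping holds the sorafenib arrays unequally on its sides, so part of the treatment difference stays in its contrast. The list counts there are no measure of chance either. Of the 4 groupings that part all 3 pairs of equal numbers, the highest other than the real one called 0 genes and 6 lists, and the 6 others, which part 1 pair each, called up to 9 lists and 0 genes.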
